A study of Mus musculus with 26 samples.

How the data were processed

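Total RNA was taken from mouse liver with a column kit, and sequencing libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here. The deposited table held estimated counts, which need not be whole, for 55642 versioned Ensembl gene IDs in 26 libraries, and 54.4% of its values above 0 were whole numbers. Per the submitters' processing notes the tools included cutadapt 3.5, which trims adapters, and Salmon 1.4.0, which assigns reads to transcripts by quasi-mapping. The same notes name the mouse builds GRCm39 and mm39. How transcript values were summed to genes is not given in the sources used here.

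Each column was matched to its library by name, and no column was left unused (0 unused columns). Groups came from the sample titles. They were wildtype on control chow (5 libraries), wildtype on CDAHFD, a high-fat diet of defined amino acids that lacks choline (6), Mtarc1 heterozygous knockout on CDAHFD (7) and Mtarc1 homozygous knockout on CDAHFD (8). The labels number the samples and do not state that each is a separate animal, so the p-values measure the spread between these samples. Gene symbols were looked up by ID in the GENCODE annotation of GRCm38, which is another build than the deposited table's. It was used for names, gene types and which genes neighbour each other, and no coordinates are given. It matched 51475 IDs (92.5%), which held 97.67% to 99.64% of the counts of a library, and unmatched genes kept their ID.

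Total estimated counts ranged from 19.73 to 29.91 M (mega counts) per library (mean 24.79 M, SD 2.65, n = 26). No library stood out as a duplicate: the chi-square per degree of freedom between libraries of one group lay between 16.6 and 131.57 over 74 pairs. Xist ranged from 724 to 1305 CPM and the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y reached at most 1.56 CPM, the pattern of female tissue in all 26 libraries, so the planned Y-linked covariate was not run. Nnt, part of which is deleted in the C57BL/6J substrain, ranged from 19.4 to 61.1 CPM.

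Estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, estimateDisp, robust quasi-likelihood fits and quasi-likelihood F tests with Benjamini-Hochberg adjustment. All 26 libraries and 4 groups entered one fit, which tested 17104 genes. The trend per Mtarc1 copy lost was fitted to the 21 CDAHFD libraries, with 16730 genes. A gene was called at an adjusted p under 0.05. The fitted common dispersion corresponds to a biological coefficient of variation of 21.5%. Fold changes are log2 values, with a standard error (SE) computed as the absolute value divided by the square root of F. CPM values are counts per M on TMM-scaled library sizes.

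Gene lists (42, of which 38 had at least 3 measured members) were tested per contrast with camera in limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), adjusted over lists. Camera with an estimated correlation and fry were run as companions, and each gene was also adjusted over the list alone. A list score per library, the mean over members of log2 CPM standardised over the 26 libraries, was compared between groups by two-sided exact permutation tests. The Mtarc1 and Mtarc2 levels were compared in the same way. Groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined.

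By that rule the text names Mtarc1 and Mtarc2; per contrast, the 6 largest rises and 6 largest falls among called genes with at least 1 CPM; per list, up to 4 called members with the lowest p, or only the member with the lowest p where none was called; members named for one contrast when the list is compared in another; and the sex chromosome genes and Nnt. Other genes are said to be chosen after their values were seen.

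Library names form 2 number series, one of 9 libraries and one of 17. These are not labelled as batches, but they are unequally spread: the 9-library series holds 1 wildtype chow, 3 wildtype CDAHFD, 3 heterozygous and 2 homozygous libraries. Values within each series are given for Mtarc1 and for the macrophage, matrix and stellate scores, and for some other values. Opposition between the diet and genotype effects was set against 100 simulated sets of unchanged groups sharing the wildtype CDAHFD libraries, and recomputed for all 20 ways of splitting those libraries 3 and 3.

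The edgeR procedure was tested on simulated data with known changes of 3 sizes, in 67, 67 and 66 genes for each group comparison. It recovered 46.3% of 1.5-fold, 82.1% of 2-fold and 97% of 4-fold changes in the diet comparison (16874 genes), and 58.2%, 83.6% and 100% in the homozygous comparison (16868 genes). For the heterozygous comparison (16861 genes) it recovered 58.2%, 88.1% and 98.5%, and for homozygous against heterozygous (16883 genes) 70.1%, 82.1% and 100%. From 6 to 12 unchanged genes were called per comparison, and at most 1 unchanged list. Simulated genes varied independently of each other, so variation shared by many genes of a library was absent. Other splits of the real libraries called up to 3427 genes, so these shares may overstate recovery in the real data.

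Alternatives were DESeq2 1.42.0, limma voom with quality weights, other scalings, other low-count filters, only the 2 groups compared, the sample number as a block, the number series as a covariate, each library left out and a threshold of 0.01. The fit within one series for the chow group of the 9-library series rests on 1 library, which is assumed to vary like the other groups. Further alternatives were chosen after the data were seen. They were the mitochondrial share as a covariate, each number series alone, permutation of groups within number series, leaving out libraries from the list scores, and leaving out the 6 CDAHFD libraries below -25 on the second principal component. Alternatives for TPM input were not needed. Exact tests used Python 3.11.15 and numpy 2.4.6, with scipy 1.17.1 for Fisher's exact test.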

Results

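Liver transcripts were measured by RNA sequencing in 26 mouse libraries. Mtarc1 encodes mitochondrial amidoxime reducing component 1, a molybdenum-dependent enzyme of the outer mitochondrial membrane. Variants of the human gene have been linked to protection from fatty liver disease. Wildtype mice on control chow (n = 5) were set against wildtype mice given CDAHFD for 2 weeks (n = 6), a choline-deficient, high-fat diet used to bring on fatty liver with inflammation and scarring. On the same diet were mice with a heterozygous (n = 7) or homozygous (n = 8) Mtarc1 knockout. Mean depth was 22.43 M (mega) counts in wildtype chow, 24.94 M in wildtype CDAHFD, 27.07 M in heterozygous and 24.14 M in homozygous libraries. The design asks what the diet changed in wildtype liver and how loss of 1 or both Mtarc1 copies altered the liver on that diet. No knockout livers on chow were measured, so a genotype difference present without the diet cannot be told apart from an altered response to it.

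Mtarc1 (ENSMUSG00000026621) followed the labelled genotypes. Its level was 305 ± 40.2 CPM (SD, n = 5) in wildtype chow, 235 ± 40.7 (n = 6) in wildtype CDAHFD, 161 ± 33.7 (n = 7) in heterozygous and 48.7 ± 10.4 (n = 8) in homozygous livers. Homozygous livers thus held 20.7% and heterozygous livers 68.3% of the wildtype CDAHFD level. All 8 homozygous libraries lay between 33.4 and 65.3 CPM, below every other library. Two-sided exact permutation tests gave p = 0.000333 for homozygous against wildtype CDAHFD (n = 8 and 6), the smallest that test can give, and p = 0.00408 for heterozygous against wildtype CDAHFD. The 2 knockout groups differed as well, with an exact permutation p of 0.000155, again the smallest possible. In the 9-library series homozygous livers held 24.8% and heterozygous livers 83.1% of the wildtype CDAHFD mean, and in the 17-library series 18.6% and 57.6%. Which part of the gene was removed is not given in the sources used here, so the remaining reads cannot be assigned to a transcript. On the diet alone wildtype Mtarc1 was at 77% of the chow level (exact permutation p = 0.0303). As a share of the raw total, that level was 90.3% of chow, with an exact permutation p of 0.234. The edgeR estimate was -0.38 ± 0.16 (SE), with an adjusted p of 0.0826. Mtarc2, the paralogous enzyme, was at 329 ± 37.6 CPM in wildtype chow, 340.5 ± 25.7 in wildtype CDAHFD, 340.1 ± 39.4 in heterozygous and 326 ± 45.9 in homozygous livers. None of its comparisons passed, with exact permutation p-values from 0.494 to 0.983.

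**Figure D1:**
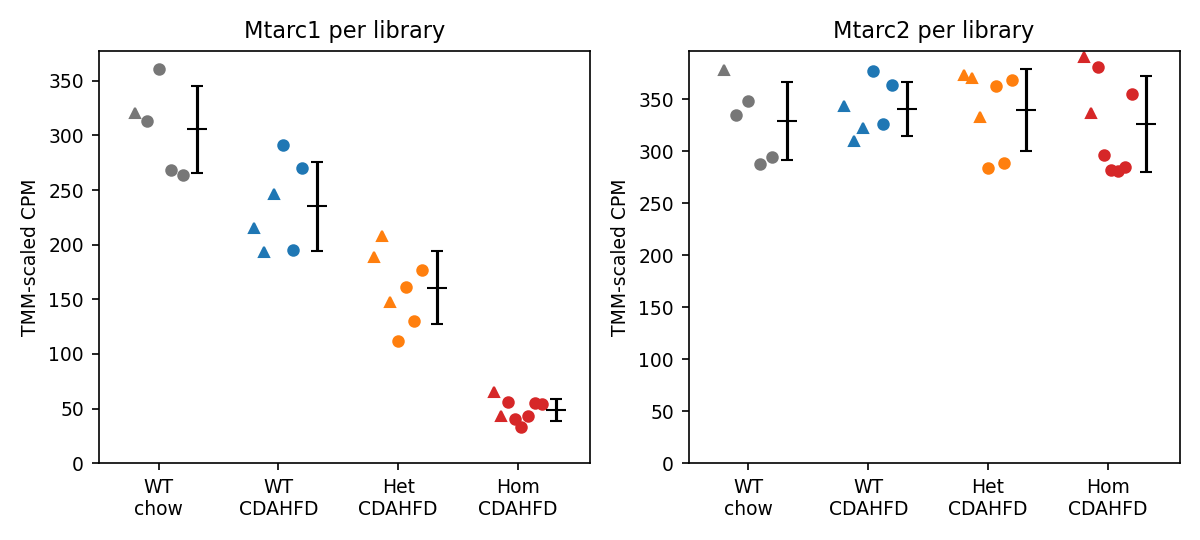
Mtarc1 (left) and Mtarc2 (right) in TMM-scaled CPM for each library, by group, with triangles for the 9-library number series, circles for the 17-library series, and the mean and SD beside the points. The 8 homozygous libraries lie between 33.4 and 65.3 CPM of Mtarc1, and Mtarc2 group means lie between 326 and 340.5 CPM.

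In wildtype liver the diet raised most measured genes of macrophages, scar matrix, inflammation and cell division, and lowered most genes of cholesterol synthesis and some of fatty acid synthesis and drug metabolism. These are counts of single genes, and as lists 0 of 38 passed with an estimated correlation. Of 17104 genes, edgeR called 4630 (27.1%), 2537 higher and 2093 lower, of which 1017 rose and 373 fell at least 2-fold. The largest rises were in Mmp12, a macrophage elastase (log2 fold change 5.86 ± 0.69), the cornified envelope gene Sprr1a (5.58 ± 0.72), Gpnmb, a glycoprotein of lipid-laden macrophages (5.56 ± 0.80), Ly6d (5.05 ± 0.68), the ubiquitin-like Ubd (4.99 ± 0.82) and the innate receptor gene Clec4e (4.88 ± 1.17). Their adjusted p-values ran from 2.27e-06 for Mmp12 to 0.00293 for Clec4e. Clec4e was near 0.0610 CPM in chow livers, and its call was lost with voom (adjusted p = 0.151). The largest falls were in Serpina4-ps1 (-6.39 ± 0.97), Serpina1e (-4.41 ± 0.79), the steroid enzyme gene Hsd3b5 (-4.20 ± 0.92), the phosphate transporter gene Slc34a2 (-3.86 ± 0.48), Scd1, which makes monounsaturated fatty acids (-3.49 ± 0.43), and the cytochrome gene Cyp2c69 (-3.30 ± 0.52). Serpina4-ps1, Serpina1e, Hsd3b5 and Cyp2c69 belong to families of near-identical genes that can share reads, so their values are uncertain. Chow livers also varied widely, at 58.9 ± 49.4 CPM (SD, n = 5) for Serpina4-ps1, 1458 ± 1210 for Serpina1e and 12.4 ± 13 for Hsd3b5.

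Markers of monocyte-derived and lipid-associated macrophages rose in 16 of 18 measured members and fell in 1, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.90. Trem2, a lipid-sensing receptor of such macrophages, rose by 3.39 ± 0.33, the pattern receptor gene Clec7a by 3.11 ± 0.32 and the lysosomal Cd68 by 1.84 ± 0.20. Camera gave an adjusted p of 2.33e-12, and the list had an adjusted p = 0.177 with an estimated correlation. Markers of resident Kupffer cells rose in 5 of 9 members (6 adjusted over the list alone), among them Vsig4 (1.02 ± 0.17) and Cd5l (1.39 ± 0.24), with a camera adjusted p of 0.00489 and an adjusted p = 0.415 with an estimated correlation. Matrix and fibrogenesis genes rose in 25 of 27 members, also 25 adjusted over the list alone, with a median of 1.43. The fibrillar collagen genes Col3a1 (2.12 ± 0.23) and Col1a1 (2.60 ± 0.28), the basement membrane collagen gene Col4a1 (1.53 ± 0.17) and Tagln, a marker of contractile cells (2.28 ± 0.24), led this list. Its camera adjusted p was 6.08e-18, and its adjusted p = 0.177 with an estimated correlation.

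Inflammatory signalling genes rose in 18 of 19 members (19 adjusted over the list alone), with a median of 1.89. The adhesion molecule gene Vcam1 rose by 2.08 ± 0.18, the monocyte attractant gene Ccl2 by 3.16 ± 0.32 and Tnfaip3, which restrains NF-kB signalling, by 1.89 ± 0.26. This list had an adjusted p = 0.179 with an estimated correlation. Interferon response genes rose in 13 of 17 members by either adjustment (adjusted over all genes and adjusted over the list alone), including Usp18 (1.43 ± 0.16) and the chemokine gene Cxcl10 (2.54 ± 0.35), with an adjusted p = 0.357 with an estimated correlation. All 16 cell division genes rose, by either adjustment (over all genes and adjusted over the list alone), with a median of 2.05. Examples were Ccnb2, a mitotic cyclin gene (2.53 ± 0.34), and Birc5 (2.22 ± 0.33), and the list had an adjusted p = 0.177 with an estimated correlation. Targets of the oxidative stress factor NRF2 rose in 8 of 16 members and fell in 1, with the same counts adjusted over the list alone. They included the heme oxygenase gene Hmox1 (1.68 ± 0.17) and Srxn1 (1.77 ± 0.23), with an adjusted p = 0.415 with an estimated correlation.

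Cholesterol synthesis and SREBP2 target genes fell in 23 of 24 members, also 23 adjusted over the list alone, with a median of -1.76. The sterol sensor gene Insig1 fell (-1.91 ± 0.24), as did the synthesis genes Lss (-2.15 ± 0.27) and Mvd (-2.81 ± 0.36). Camera gave an adjusted p of 2.48e-18, and the list had an adjusted p = 0.211 with an estimated correlation. Of 18 genes of fatty acid synthesis 9 fell and 1 rose (10 fell and 1 rose adjusted over the list alone), with a median of -0.69. Scd1, the acetyl-CoA synthetase gene Acss2 (-2.15 ± 0.26) and the fatty acid synthase gene Fasn (-1.73 ± 0.29) were among the falls, and the list had an adjusted p = 0.415 with an estimated correlation. Of 12 xenobiotic genes 5 fell (6 adjusted over the list alone), led by the carboxylesterase gene Ces2a (-2.45 ± 0.23) and the cytochrome genes Cyp2b10 (-2.58 ± 0.31) and Cyp3a11 (-1.22 ± 0.17), with an adjusted p = 0.415 with an estimated correlation. Of 17 bile acid genes 9 fell and 1 rose, with the same counts adjusted over the list alone. Cyp27a1, an enzyme of bile acid synthesis, fell (-1.12 ± 0.12), as did the bile salt export pump gene Abcb11 (-0.67 ± 0.14), with an adjusted p = 0.437 with an estimated correlation.

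Of 19 triglyceride and lipid droplet genes 5 rose, 1 fell and 13 were not called, with the same counts adjusted over the list alone. Cidec, which enlarges lipid droplets, rose by 4.56 ± 0.62 and the droplet protein gene Hsd17b13 by 1.19 ± 0.15, with an adjusted p = 0.415 for the list with an estimated correlation. Secreted hepatocyte proteins fell in 6 of 12 members (8 adjusted over the list alone), among them the transthyretin gene Ttr (-0.64 ± 0.13), with an adjusted p = 0.415 with an estimated correlation. Transcripts of the mitochondrial genome fell in 9 of 13 members (13 adjusted over the list alone), including mt-Atp6 (-0.90 ± 0.23) and mt-Co3 (-0.63 ± 0.17), with an adjusted p = 0.415 with an estimated correlation. Their share of all counts was 13.13% ± 2.98 (SD, n = 5) in chow and 10.09% ± 2.33 (n = 6) on the diet, with an exact permutation p of 0.0866. The 20 most abundant genes took 29.47% of chow counts and 24.88% of diet counts (exact permutation adjusted p = 0.0433).

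In all, 20 of 38 lists passed camera for the diet, 10 up and 10 down, 0 with an estimated correlation and 24 by fry. Per-library scores differed for 16 lists by the exact permutation test (adjusted over 38 lists), and for 11 with groups permuted within number series. For the macrophage list the difference was 1.82 pooled and 1.68 within series, with all 6 diet livers above all chow livers (exact permutation p = 0.00216, the smallest possible). For the matrix list it was 2.05 pooled and 1.86 within series. The number of called diet genes was 2264 in the 17-library series alone and 418 in the 9-library series, which has 1 chow library.

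**Figure D2:**
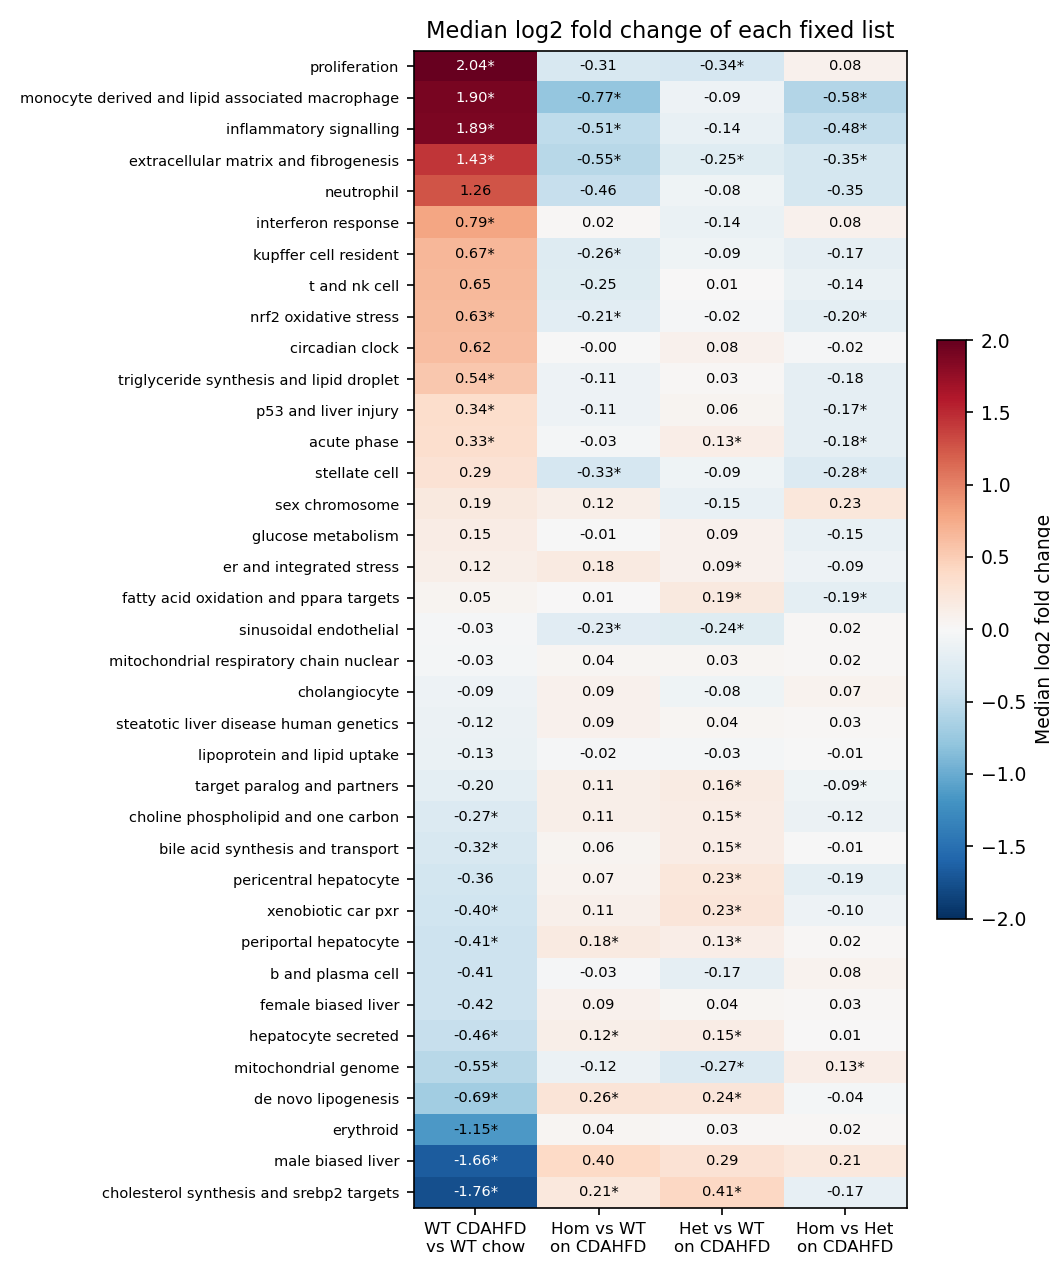
Median log2 fold change of each gene list (vertical axis) in the diet, homozygous, heterozygous and homozygous against heterozygous comparisons (horizontal axis), with an asterisk where camera at the preset correlation passed an adjusted p of 0.05. The macrophage list has medians of 1.90, -0.77, -0.09 and -0.58, and the cholesterol list of -1.76, 0.21, 0.41 and -0.17.

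Homozygous knockout livers on the diet had lower levels of macrophage and matrix genes than wildtype livers on the diet as lists, while edgeR called none of these genes singly. These calls were made by camera at its preset correlation and did not hold with an estimated correlation, where the macrophage list had an adjusted p = 0.169 and the matrix list an adjusted p = 0.193. The matrix score per library also missed the adjusted threshold (exact permutation adjusted p = 0.114). The macrophage list had a median log2 fold change of -0.77, with all 18 members below 0, and the matrix list one of -0.55, with 26 of 27 members below 0. Mtarc1 itself was the 1 gene called by edgeR of 17104 (-2.27 ± 0.15, adjusted p = 8.02e-11). An unadjusted p under 0.05 was found for 1705 genes where 855 are expected on average by chance. How far a chance count strays from that average when genes vary together was not tested. DESeq2 called 47 genes, 44 of them lower, and voom called 1. The DESeq2 genes included 6 of the 27 matrix genes and 3 of the 18 macrophage genes, all lower. They were the contractile genes Tagln (DESeq2 adjusted p = 0.0039) and Acta2 (0.0248), the collagen genes Col3a1 (0.0333), Col4a2 (0.0333) and Col1a2 (0.0413), the collagen crosslinking gene Loxl2 (0.0439), and Cd63 (0.028), Trem2 (0.0359) and Clec7a (0.0491). Of these Acta2, Col4a2, Col1a2 and Loxl2 were chosen here after their values were seen.

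Adjusted over the list alone, 13 of 18 macrophage genes and 22 of 27 matrix genes were lower, against 0 of each adjusted over all genes. By edgeR the lysosomal membrane gene Cd63 was at -0.98 ± 0.23 (adjusted p = 0.165), Trem2 at -1.03 ± 0.24 (0.165), Clec7a at -0.94 ± 0.24 (0.181) and Cd68 at -0.64 ± 0.17 (0.181). Mean Trem2 was 11.6 CPM in wildtype and 5.68 CPM in homozygous livers on the diet, against 1.10 CPM in chow livers. Gpnmb, chosen here after its values were seen, was at -1.92 ± 0.50 (adjusted p = 0.181). In the matrix list Tagln was at -1.02 ± 0.20 (adjusted p = 0.103), Col3a1 at -0.81 ± 0.19 (0.165), Col1a1 at -0.83 ± 0.23 (0.202) and Col4a1 at -0.55 ± 0.15 (0.188). Without wildtype CDAHFD sample 4 Tagln passed, at -1.12 (adjusted p = 0.0339). Camera gave adjusted p-values of 3.01e-14 for macrophages and 1.26e-18 for matrix, and fry 0.0321 and 0.0470.

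Per-library scores gave the spread between livers. The macrophage score was 0.75 lower in homozygous livers, with 8 of 8 below the wildtype mean and 7 below every wildtype liver (exact permutation p = 0.00167, adjusted p = 0.0443). Within number series the difference was -0.65 (exact permutation p = 0.0167, adjusted p = 0.317), and it was -1.11 in the 9-library series and -0.38 in the 17-library series. Wildtype CDAHFD samples 2 and 3, both of the 9-library series, had the 2 highest macrophage and matrix scores of that group. Without both, a choice made after the scores were seen that lowers the difference by construction, the macrophage difference was -0.40 (exact permutation p = 0.0182). The stellate cell score, over markers of the vitamin A storing cells that make scar matrix, was 0.85 lower (exact permutation p = 0.00233, adjusted p = 0.0443). Within series it differed by -0.88 (exact permutation p = 0.00714, adjusted p = 0.271), at -1.28 in the 9-library and -0.64 in the 17-library series. The matrix score was 0.83 lower in homozygous livers (exact permutation p = 0.00899, adjusted p = 0.114). Within series it differed by -0.69 (exact permutation p = 0.0548), at -1.45 in the 9-library series and -0.24 in the 17-library series. Without wildtype CDAHFD samples 2 and 3 it was -0.33 (exact permutation p = 0.097). No list score stayed past the adjusted threshold within series: 0 of 38 did, with 3 at an unadjusted exact p under 0.05.

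**Figure D3:**
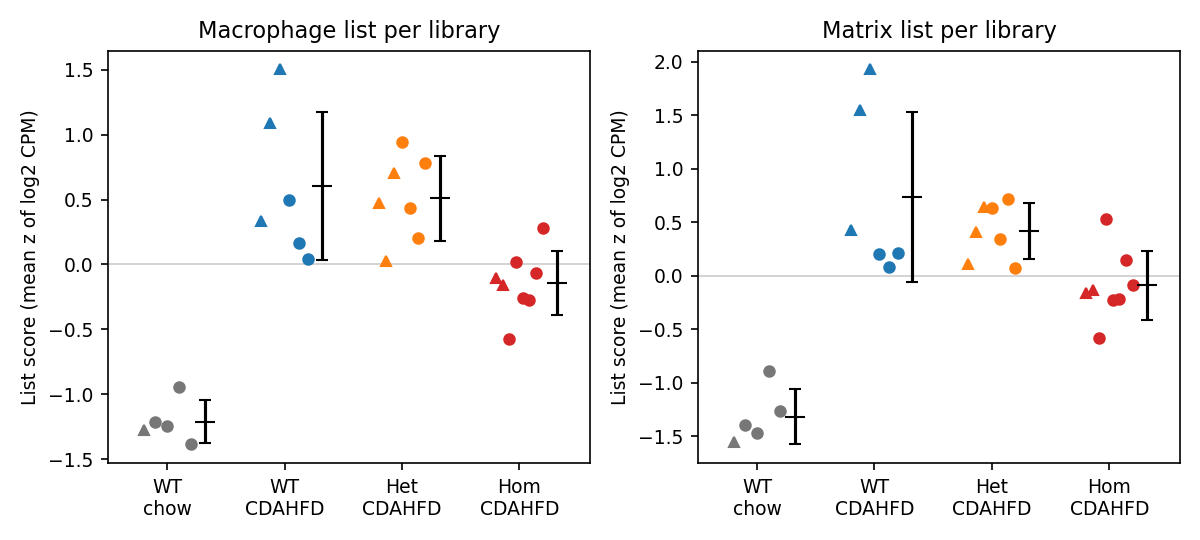
Per-library score of the macrophage list (left) and the matrix list (right), the mean of standardised log2 CPM over list members, by group, with triangles for the 9-library number series, circles for the 17-library series, and the mean and SD beside the points. Homozygous livers lie 0.75 below wildtype CDAHFD livers on average for macrophages and 0.83 below for matrix.

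Macrophage markers were lower relative to those of other cell types. Their mean log2 CPM minus that of endothelial, lymphocyte, neutrophil and bile duct markers was 2.44 ± 0.16 (SD, n = 8) in homozygous and 2.96 ± 0.37 (n = 6) in wildtype livers, with an exact permutation p of 0.000999. Within series this difference was -0.46 (exact permutation p = 0.00833). Inflammatory signalling genes had a median of -0.51 with all 19 members below 0, and by edgeR 3 passed adjusted over the list alone against 0 over all genes. Ccl2 was at -1.05 ± 0.24 (edgeR adjusted p = 0.165) and was the 1 member called by DESeq2 (adjusted p = 0.0333). The inflammatory list had an adjusted p = 0.492 with an estimated correlation. Stellate markers had a median of -0.33 with all 10 members below 0, of which 2 passed adjusted over the list alone. One was the stellate transcription factor gene Hand2 (-0.41 ± 0.13), and the list had an adjusted p = 0.492 with an estimated correlation.

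Lipid synthesis lists lay above 0 in homozygous livers. The fatty acid synthesis list had a median of 0.26 with 16 of 18 members above 0, of which 1 passed adjusted over the list alone and 0 over all genes. That was Srebf1, which drives lipid synthesis (0.67 ± 0.20, list-alone adjusted p = 0.0434), and Fasn was at 0.76 ± 0.26. The cholesterol list had a median of 0.21 with all 24 members above 0, of which 0 passed adjusted over the list alone. Insig1 was at 0.71 ± 0.21 (adjusted p = 0.234). Camera gave adjusted p-values of 0.000256 and 4.19e-05 for the lipid synthesis and cholesterol lists, against an adjusted p = 0.556 and 0.738 with an estimated correlation. In the 17-library series alone neither list passed camera, at medians of 0.15 (adjusted p = 0.186) and 0.05 (adjusted p = 0.684). Without the 6 diet livers lowest on the second component the cholesterol median was 0.04 (adjusted p = 0.768).

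In all, 11 of 38 lists passed camera for the homozygous comparison, 7 down and 4 up, 0 with an estimated correlation and 2 by fry. The others were sinusoidal endothelial (-0.23), Kupffer (-0.26) and NRF2 target (-0.21) lists, and hepatocyte secreted (0.12) and periportal (0.18) lists, given as medians, with no member called adjusted over the list alone. The hepatocyte secreted (-0.015) and periportal (-0.029) medians turned in the 17-library series and the Kupffer median (0.041) in the 9-library series. Each of these 5 had an adjusted p = 0.738 with an estimated correlation. Near Mtarc1, where a strain difference could travel with the targeted locus, edgeR called 0 of 69 genes within 5 Mb. Apart from Mtarc1 it also called 0 of the 17034 other genes, so this count decides nothing. At an unadjusted p under 0.05 there were 8 (11.6%) within 5 Mb against 9.95% of all other genes (Fisher's exact p = 0.685). Within 20 Mb there were 33 of 257 (12.8%) against 9.91% (Fisher's exact p = 0.14).

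In heterozygous knockout livers edgeR called no single gene against wildtype livers on the diet, and no list call held with an estimated correlation. Of 17104 genes 0 were called, with 1444 at an unadjusted p under 0.05 where 855 are expected on average by chance. Other splits of these libraries called up to 3427 genes at an adjusted p under 0.05, so other groupings can lie far above 855. DESeq2 called 3 (1739 unadjusted) and voom 0 (2636 unadjusted). The 3 DESeq2 genes, chosen here after their values were seen, were Gm7969, Gm14440 and Rpl36a-ps2. Gm14440 was at 0 CPM in heterozygous livers and at 1.75 ± 2.71 CPM (SD, n = 6) in wildtype livers, and Rpl36a-ps2 at 0 and 2.02 ± 3.18 CPM, so no fold change is given. Mtarc1 was at -0.55 ± 0.15 (adjusted p = 0.569, list-alone adjusted p = 0.0127). The endoplasmic reticulum chaperone gene Hspa5 was at 0.54 ± 0.16 (list-alone adjusted p = 0.0339), and Tagln at -0.66 ± 0.20 (list-alone adjusted p = 0.0439).

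The cholesterol list lay highest among the heterozygous lists, with a median of 0.41, all 24 members above 0 and 0 called over all genes or adjusted over the list alone. Its camera adjusted p was 1.11e-07, and it had an adjusted p = 0.710 with an estimated correlation. Its score per library differed by 0.57 (exact permutation p = 0.129), at 1.13 in the 9-library and 0.05 in the 17-library series. In the 17-library series alone the list did not pass camera (median 0.15, adjusted p = 0.713). Insig1 was at 0.58 ± 0.22. The mitochondrial genome list had a median of -0.27 with all 13 members below 0, of which 0 passed adjusted over the list alone, and mt-Nd6 was at -0.44 ± 0.20. Sinusoidal endothelial markers had a median of -0.24 with all 10 members below 0, of which 0 passed adjusted over the list alone, and Pecam1, an endothelial adhesion gene, was at -0.33 ± 0.16. The matrix list had a median of -0.25, of which 2 members passed adjusted over the list alone. In the 17-library series alone its median was 0.19, with a camera call in the opposite direction. Macrophage markers had a median of -0.09 with 0 passing adjusted over the list alone, and Trem2 was at -0.11 ± 0.24. Both turned in the 17-library series alone (0.41 and 0.54), and the list with voom (0.08). The macrophage score differed by -0.57 in the 9-library and 0.36 in the 17-library series. In all, 16 of 38 lists passed camera, 12 up and 4 down, with 0 by fry and an adjusted p = 0.710 with an estimated correlation for each of those 16. Exact permutation tests of per-library scores gave 0 of 38 lists past the adjusted threshold and 1 at an unadjusted p under 0.05.

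The direct comparison of homozygous with heterozygous livers tested the difference between the 2 knockouts. Macrophage markers were lower in homozygous livers, with a median of -0.58, 17 of 18 members below 0 and 12 passing adjusted over the list alone, against 0 over all genes. Trem2 was at -0.92 ± 0.23 (adjusted p = 0.339), Clec7a at -0.89 ± 0.23 (adjusted p = 0.339) and Cd68 at -0.48 ± 0.16 (adjusted p = 0.483). The list had an adjusted p = 0.182 with an estimated correlation. Its score was 0.65 lower in homozygous livers, with 8 of 8 below the heterozygous mean (exact permutation p = 0.00109, adjusted p = 0.0413). Within series the difference was -0.67 (exact permutation p = 0.0019, adjusted p = 0.0724), at -0.53 in the 9-library and -0.74 in the 17-library series. The matrix list had a median of -0.35 and 0 members passing adjusted over the list alone, with the matrix gene Lum at -0.58 ± 0.19, and an adjusted p = 0.779 with an estimated correlation. The matrix score differed by -0.51 (exact permutation p = 0.00637, adjusted p = 0.121). Permuted within series it differed by -0.52 (exact permutation p = 0.00905, adjusted p = 0.172), at -0.53 in the 9-library and -0.51 in the 17-library series. The stellate score differed by -0.53 (exact permutation p = 0.1915). Angptl8, a regulator of lipoprotein lipase, was at 1.49 ± 0.37 (list-alone adjusted p = 0.00985). Mtarc1 was the 1 gene called by edgeR (-1.72 ± 0.14, adjusted p = 2.36e-08), with 1219 genes at an unadjusted p under 0.05, 15 called by DESeq2 and 1 by voom. Most of the 15 DESeq2 genes were processed pseudogenes, and these were all higher in homozygous livers. In all, 10 lists passed camera, 1 up and 9 down, 0 with an estimated correlation and 0 by fry.

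Per Mtarc1 copy lost, over the 21 diet libraries, Mtarc1 fell by 1.17 ± 0.11 on the log2 scale (adjusted p = 4.13e-06) and was the 1 gene called of 16730. DESeq2 called 63 genes and voom 1, and 1626 genes had an unadjusted p under 0.05. Tagln was at -0.50 ± 0.10 (adjusted p = 0.153) and Trem2 at -0.53 ± 0.14 (adjusted p = 0.235) per copy. The matrix list had a median slope of -0.28 with 22 of 27 members passing adjusted over the list alone, and the macrophage list one of -0.39 with 12 of 18. Both had an adjusted p = 0.247 with an estimated correlation. A slope assumes equal steps per copy, which the macrophage scores did not show. They differed from wildtype CDAHFD by -0.095 in heterozygous and -0.747 in homozygous livers, and the matrix scores by -0.318 and -0.827. In all, 11 of 38 lists passed camera, 0 with an estimated correlation and 0 by fry.

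The genotype effects were compared with the diet effect gene by gene, since both use the wildtype CDAHFD libraries. Of the 4630 diet genes, 80.2% had a homozygous fold change opposite in sign to their diet change. Unchanged groups sharing those libraries gave a median of 61.9% and a range of 23.2% to 87.1%, and 7 of 100 simulations were as opposed. Over all genes the covariance of the fold changes was -0.0827, against a simulated median of -0.0289 and a lowest simulated value of -0.154. With the wildtype CDAHFD libraries split 3 and 3, the share was 64.9% to 85.9% (median 77.8%) and the covariance was below 0 in 20 of 20 splits (median -0.0581). The genes of that share were called with all 6 wildtype CDAHFD libraries, so splitting does not fully remove the sharing from it. The 20 splits also overlap in their libraries and are not independent. For heterozygous livers the share was 59.1%, against a simulated median of 57.1% with 43 of 100 simulations as opposed. Their covariance was -0.0198, against a simulated median of -0.0178, and was below 0 in 9 of 20 splits (median 0.0054). Without knockout livers on chow, opposite signs do not show for either genotype that the response to the diet was altered.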

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

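Tests of the mitochondrial share, of a lower share of all nonhepatocyte cells and of ribosomal protein copies were chosen after the results were seen, as were permutation within number series, added after the pooled list scores, and the genomic DNA test, added after the pseudogene rise, though for these 2 the outcome that would count for each cause was written before the test was run, while the tests of shared libraries and other splits were chosen before.

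Homozygous livers had 30.3% of the heterozygous Mtarc1 level, and their macrophage score differed from that of heterozygous livers by -0.65. Both knockouts were compared with the same wildtype livers, and the difference between the knockouts passed its own pooled exact permutation test in each case. With groups permuted within number series, 0 of 38 list scores passed the adjusted threshold for this comparison, the macrophage score included.

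Single libraries standing far from the rest of their group were looked for in 508 groups of values, of which 19 passed the limit where about 25 are expected by chance, since chance alone marks about 1 in 20 groups. Heterozygous sample 4 accounted for 6 of them. It was lowest for the fatty acid synthesis score (gap of 0.586 of the group's range), the xenobiotic score (0.573), the hepatocyte secreted score (0.611), Ces2a (0.687), Cyp2b10 (0.605) and Scd1 (0.614). Heterozygous sample 2 was lowest for the bile duct score (0.592) and A1bg (0.681), sample 6 lowest for Bhmt (0.613) and sample 7 highest for Cyp3a11 (0.779). Homozygous sample 4 was highest for the p53 target score (0.564) and Phlda3 (0.527), and sample 7 for the B and plasma cell score (0.572). Among wildtype CDAHFD libraries, sample 3 was lowest for Pcyt2 (0.683), sample 4 for Serpina4-ps1 (0.629) and sample 6 for Asns (0.689). Among chow libraries, sample 3 was highest for the genes flanking Mtarc1 (0.723), sample 1 lowest for Arntl (0.753) and sample 5 lowest for Srxn1 (0.711).

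Other splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included, show which counts other groupings gave. For the diet 1 of 100 splits, the real one, reached the 4630 genes, with 3390 the highest of the others. That other split grouped all 5 chow libraries with wildtype CDAHFD sample 6, so it kept most of the diet contrast. These 100 are part of 462 possible splits. For homozygous livers 3 of 100 reached the real count of 1 gene, with 8 the highest other, and for the trend 3 of 100 reached 1 gene, with 1 the highest other. All 100 reached the 0 genes of heterozygous livers, with 3427 the highest other, and 8 of 100 reached the 1 gene of homozygous against heterozygous livers, with 1529 the highest other. In the homozygous, trend and homozygous against heterozygous comparisons the real gene was Mtarc1, the targeted gene itself. Those gene counts therefore show nothing about effects on other genes. Counts of lists did not stand out from other splits in any comparison. For the diet, uneven splits keep part of the diet contrast, so they do not show what chance alone gives for lists. As many lists were reached by 12 of 100 splits for the diet (real 20, highest other 23), 41 for homozygous (11 and 24), 26 for heterozygous (16 and 27), 57 for homozygous against heterozygous (10 and 26) and 52 for the trend (11 and 24). The splits with 3427, 2833 and 1529 genes point to a structure of the CDAHFD libraries that crosses genotypes but is unequally spread over them. The split with 3427 set wildtype samples 1, 2 and 5 and heterozygous samples 1, 4 and 5 against the others. Of these 6 libraries 5, heterozygous sample 1 being the exception, were lower on the second principal component than the other wildtype and heterozygous CDAHFD libraries, and both number series were among the 6. The CDAHFD libraries below -25 on that component were wildtype samples 1, 2 and 5, heterozygous sample 4 and homozygous samples 4 and 7. Each had a higher mitochondrial share of counts (11.205% or more) than every other CDAHFD library (10.454% or less). What sets these libraries apart was not tested.

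The lower macrophage and matrix scores of homozygous livers were weighed against 3 technical explanations. The macrophage score differed with groups permuted within series (exact permutation p = 0.0167), the outcome written beforehand against number series as its cause. That p was unadjusted, and adjusted over 38 lists it was 0.317, so number series are not excluded. The matrix score missed the threshold there (exact permutation p = 0.0548), the outcome written before that permutation for number series as its cause. With the mitochondrial share as a covariate the median log2 fold change of the 45 members of both lists was -0.60, against -0.60 without it, which argues against that share. A lower share of all nonhepatocyte cells is argued against for the macrophage list. That list was lower relative to other cell types, stellate cells left out (exact permutation p = 0.000999). With stellate cells included the macrophage difference was -0.50 (exact permutation p = 0.00233). Such a lower share cannot be told apart for the matrix list, whose difference from other cell types, stellate cells included, was -0.36 (exact permutation p = 0.0526). Number series stay open for both lists, and cell share for the matrix list. The size of the macrophage difference is uncertain (-1.11 and -0.38 in the 9-library and 17-library series), and macrophage number and state were not tested. The second component structure was not among the explanations weighed here. It is unequally spread over the genotypes, so it stays open for both lists. Both lists stayed lower in homozygous livers without the libraries lowest on it.

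The opposition of genotype and diet effects was weighed against the wildtype CDAHFD libraries that both comparisons share. For homozygous livers the covariance of -0.0827 lay inside the simulated range of -0.154 to 0.041, the outcome set beforehand for shared libraries as the cause, so that explanation stays open. With split controls the covariance was below 0 in 20 of 20 splits (median -0.0581). Shared libraries alone would not need this, since each split uses different wildtype libraries for the 2 effects. The 20 splits overlap in their libraries, so they are not 20 independent tests. The second component structure still crosses such splits. For heterozygous livers the median over splits was 0.0054, so sharing could account for their opposition.

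Processed pseudogenes, 348 tested, had a median log2 fold change of 0.54 in homozygous against heterozygous livers, with 141 of the 143 at an unadjusted p under 0.05 higher and 0 called by edgeR. Most of the 15 genes that DESeq2 called for this comparison were processed pseudogenes, all higher in homozygous livers. The mean log2 CPM of the 348 differed by 0.35 (exact permutation p = 0.0225, adjusted over 12 tests p = 0.135), and by 0.24 without homozygous sample 4, the highest of samples 4, 7 and 8 that stood above the other homozygous livers. With each library left out in turn, the unadjusted exact permutation p of homozygous against heterozygous livers ran from 0.00408 to 0.0486. Homozygous and wildtype CDAHFD livers differed by 0.22 (exact permutation p = 0.229). There the median log2 fold change was 0.355, with 102 of the 113 pseudogenes at an unadjusted p under 0.05 higher. The share of counts was 0.123% in homozygous and 0.104% in heterozygous livers (exact permutation p = 0.33), so the rise itself is uncertain. Genomic DNA in the homozygous libraries is argued against by olfactory and vomeronasal receptor genes, whose summed CPM was 0.986 times the heterozygous level (exact permutation p = 0.879). Copies not named after ribosomal protein genes had a median of 0.51, but names give a ribosomal parent for 25 of the 348 copies, so this test decides nothing and misplaced reads of ribosomal protein genes stay open, and no biological explanation was tested.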

How the results depend on the processing

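The mitochondrial covariate, each number series alone, permutation within series, libraries left out of list scores and the exclusion on the second component were chosen after the data were seen, and the other alternatives before. Called diet genes numbered 2264 in the 17-library series, 418 in the 9-library series and 2767 at an adjusted p under 0.01. The stricter limit lowers the count by construction. Whether fewer samples account for the lower counts in each series alone was not tested. Called homozygous genes numbered 47 with DESeq2 and 2 in the 9-library series, heterozygous genes 3 with DESeq2, homozygous against heterozygous genes 15 with DESeq2 and 0 in the 9-library series, and trend genes 63 with DESeq2, 2 without a low-count filter and 2 in the 9-library series. Lists passing numbered 0 in all 5 comparisons with an estimated correlation. By fry they numbered 2 (homozygous), 0 (heterozygous), 0 (homozygous against heterozygous) and 0 (trend). In the 9-library series they numbered 19 (homozygous), 26 (heterozygous) and 23 (trend), and in the 17-library series 10 (heterozygous). Without the libraries lowest on the second component they numbered 11 (diet), 7 (homozygous), 10 (heterozygous) and 7 (trend). At an adjusted p under 0.01 they numbered 7 (homozygous) and 7 (heterozygous), and with the mitochondrial covariate 8 (heterozygous). List scores past the adjusted threshold numbered 0 within series for homozygous and 0 for homozygous against heterozygous livers. Mtarc1 on the diet was at 90.3% of chow as a share of the raw total, no longer past the threshold. Among diet genes at an adjusted p under 0.01 and 2-fold, 90.0% were opposed in homozygous livers, where unchanged groups sharing the wildtype libraries gave a median of 60.6%, a range of 17.7% to 91.7% and 3 of 100 simulations as opposed. With the sample number as a block, called genes numbered 3628 (diet), 1 (homozygous), 0 (heterozygous), 1 (homozygous against heterozygous) and 2 (trend). The labels do not say that the numbers pair libraries. Leaving out 1 library gave 1 to 4 homozygous genes (4 without wildtype CDAHFD sample 4), 6 to 18 heterozygous lists (6 without heterozygous sample 1), 8 to 16 lists for homozygous against heterozygous livers (16 without heterozygous sample 4) and 1 to 2 trend genes. Some log2 fold changes changed sign. In the 17-library series they were, for homozygous livers, the periportal (-0.029) and hepatocyte secreted (-0.015) lists. For heterozygous livers they were the target (0.068), fatty acid synthesis (0.070), bile acid (-0.055), matrix (0.186), xenobiotic (-0.074), periportal (-0.179), hepatocyte secreted (-0.089) and macrophage (0.415) lists, and Trem2 (0.539), Cd68 (0.208), Col3a1 (0.175) and Clec7a (0.653). For the target and fatty acid synthesis lists the test's direction, not the median, turned. In the 9-library series they were the Kupffer list (0.041 homozygous, 0.017 trend), Vsig4 (0.041 homozygous), Arntl (0.110 diet) and Mtarc2 (-0.216 diet, 0.166 homozygous, 0.147 heterozygous, 0.019 homozygous against heterozygous, 0.086 trend). Mtarc2 was also at -0.031 on the diet with the mitochondrial covariate, and in heterozygous livers at 0.002 with DESeq2, 0.000 with RLE scaling, 0.001 without a low-count filter and 0.001 with the number series covariate. Heterozygous values also changed sign for the macrophage list (0.078) and Clec7a (0.187) with voom, for Clec7a with the sample number as a block (0.011), for the xenobiotic list with the mitochondrial covariate (0.049, in the direction of the test) and for the periportal list without the second component libraries (-0.051). The trend of the cholesterol list was -0.011 without those libraries. Leaving out 1 library gave, for heterozygous livers, -0.208 to 0.110 for the macrophage list, -0.296 to 0.084 for Trem2, -0.173 to 0.328 for Clec7a and -0.039 to 0.034 for Mtarc2. Except for the stricter limit, the cause of these changes was not tested. The macrophage and matrix lists of homozygous livers stayed below 0 under each alternative run. Without wildtype CDAHFD samples 2 and 3, chosen after the scores were seen, the matrix score of homozygous livers differed by -0.33, no longer past the unadjusted threshold, and the macrophage score by -0.40. Depth limits genes near the floor such as Clec4e, at 0.0610 CPM in chow livers.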

Other observations

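The comparisons of lists in this part were fixed before the data were seen, and the choice of which to describe was made afterwards. On the diet acute phase genes rose in 8 of 18 members and fell in 2 (9 and 2 adjusted over the list alone), with an adjusted p = 0.437 with an estimated correlation. Lcn2, an iron-sequestering protein gene, rose by 4.09 ± 0.51 and the serum amyloid gene Saa1 by 3.42 ± 0.43. Targets of p53 and injury genes rose in 4 of 12 members (6 adjusted over the list alone), with an adjusted p = 0.415 with an estimated correlation, among them Phlda3 (2.25 ± 0.33) and the cell cycle inhibitor gene Cdkn1a (1.80 ± 0.42). Hemoglobin and other erythroid genes fell in 4 of 5 members and 1 rose, with the same counts adjusted over the list alone and an adjusted p = 0.415 with an estimated correlation. Hba-a1 was at -1.26 ± 0.24. Genes of choline, phospholipid and one-carbon metabolism fell in 4 of 23 members and 1 rose, with the same counts adjusted over the list alone and an adjusted p = 0.437 with an estimated correlation. Bhmt, which uses betaine made from choline, was at -0.98 ± 0.17 and Pcyt2, of phosphatidylethanolamine synthesis, at -0.82 ± 0.14.

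Genes with male-biased liver expression fell in 5 of 9 members and 1 rose on the diet, with the same counts adjusted over the list alone and an adjusted p = 0.415 with an estimated correlation, including Elovl3 (-1.96 ± 0.32). Female-biased genes fell in 4 of 12, also 4 adjusted over the list alone, and that list did not pass camera (adjusted p = 0.0576). Periportal genes fell in 3 of 12 members (4 adjusted over the list alone), with an adjusted p = 0.5 with an estimated correlation, among them the glutaminase gene Gls2 (adjusted p = 0.000207). Of 18 lipid uptake genes, which did not pass camera as a list, 8 fell and 5 rose (8 and 6 adjusted over the list alone), with a median of -0.13 and 11 members below 0. The apolipoprotein gene Apoa4 rose by 2.65 ± 0.28, the fatty acid transporter gene Cd36 by 1.74 ± 0.24 and the lipase gene Lpl by 1.59 ± 0.26. Angptl8 fell (-2.29 ± 0.43). In homozygous livers Angptl8 was at 1.47 ± 0.39 and Lpl at -0.70 ± 0.22 against wildtype CDAHFD livers, with list-alone adjusted p-values of 0.0186 and 0.0285 and adjusted p-values over all genes of 0.202 and 0.252. Hspa5 was at 0.52 ± 0.15 in homozygous livers (list-alone adjusted p = 0.0387, adjusted p = 0.239), beside 0.54 ± 0.16 in heterozygous livers.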
